A study of Mus musculus with 34 samples.

How the data were processed

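Bulk RNA-seq was made from 34 mouse samples: 10 kidneys, 14 kidney explants and 10 progenitor assembloids. RNA was prepared with column kits from Zymo Research (Direct-zol RNA MicroPrep or Quick-RNA Microprep), and libraries were built by NovoGene, per the labels. The processing tools named are STAR 2.7.8a and Partek, with the builds mm39 and mm10, per the submitters' processing notes. Gene coordinates in the deposited table fit mm39: of 22685 nuclear genes shared with an mm10 annotation, 473 had the same start. All coordinates given are those of the table, on mm39. The read counter, any filter on genes, and the strand setting are not given in the sources used here.

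The deposited values are a TMM-normalized expression signal per gene, per the name of the deposited table, and are not counts. How the authors scaled and offset the signal before deposit is not given in the sources used here. The table holds 23331 genes in 34 columns, with column totals of 879095 to 1503681 (median 962126). No value is 0. In each column the lowest value, called 1 step here, lies between 0.03505 and 0.11881, and of the values up to 20 steps 88.9 to 94.5% were whole multiples within 0.1 step. That share was too low to recover reads, so no count test was run. Column totals divided by the step gave an implied depth of 7772154 to 28457465 steps per library (median 19097838), with the second lowest at 15243510. For a named gene at 1 step in all libraries of a compared group a lower bound on the fold is given beside the fitted change, against a floor of 3 steps per library; floors and bounds cover counting error only. Fitted log2 changes of such genes depend on the pseudocount and are smaller than the bound.

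The samples of a group were compared before averaging. Their log2 values correlated at 0.9834 to 0.9963, and the chi-square over degrees of freedom of each pair was 3.65 to 34.91, so no pair lay within sampling noise and none was counted once. The columns of the P9 kidneys carry the name D9 and those of the assembloids SK, and each was matched to its sample through the sample's description, which holds the column name. The table held 0 columns of other samples.

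Values were tested as log2(value + 0.962), where the pseudocount is 1 ppm of the median column total. Genes with a value of at least the pseudocount in 2 samples were kept, 19264 in all. A linear model with 17 group means was fitted to all 34 samples with limma 3.58.1 in R 4.3.3, with 17 residual degrees of freedom and empirical Bayes moderation with trend and robust settings (median prior degrees of freedom 9.93). Where a library was left out, the lone sample of its group was assumed to vary like the other groups. For comparisons of D19 assembloids the mean of r1 and r2 was used. A gene was called with a Benjamini-Hochberg adjusted p under 0.05 and a log2 change of at least 1 in size. The fold changes are on the log2(value + pseudocount) scale, which understates those of low genes. Between P0 and E12.5, 3748 of the 3780 genes past the fold threshold also passed the p threshold, so there the fold threshold sets the count.

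The comparisons, the test, the alternatives and 26 gene lists with 285 genes, covering kidney cell types, other cell types and processes, were fixed before the data were examined. The rule for genes named in the text was fixed then too. In each comparison it takes, among called genes with a mean of at least 10 times the pseudocount in the higher group and an assigned symbol, the 6 with the largest positive and the 6 with the largest negative log2 change. For each list described it adds up to 4 members, the called ones with the largest change or, where none was called, those with the highest mean. Some genes that the rule takes are not reported here. Genes outside the rule are said to have been chosen after their values were seen. Lists were tested with camera from limma, with the preset correlation of 0.01 and again with a correlation estimated for each list, and adjusted over the lists of a comparison. The variance trend in camera was not fixed beforehand and was switched on after the default had been tried; the default is given as an alternative. Of 312 list results, 24 had a median, mean and test that differed in sign, and none of these passed the threshold with either correlation. For the 11 comparisons of groups the list medians were also computed with members at 1 step set to their bound. Of 286 medians 26 moved, by up to 2.11, all away from 0, and 0 changed sign.

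The model and the list test were tested on simulated data. With 200 of 19264 genes changed, 50 at each fold and all with means of at least 10 times the pseudocount, limma recovered 38% at 2-fold, 100% at 3-fold, 98% at 4-fold and 100% at 8-fold in the v2 against v1 explant design. In the assembloid against P0 design the shares were 42, 96, 100 and 98%, and in the difference of the D3 to D19 changes 52, 94, 98 and 100%. Of the 19052 genes neither among these 200 nor among the 12 of a shifted list, 3, 1 and 6 were called in these designs, and camera found the shifted list of 26 with both correlations and 0 others. The simulated noise was drawn separately for each gene. The simulation therefore cannot show how often camera calls lists of correlated genes wrongly with the preset correlation. The alternatives were a smaller pseudocount (divided by 4) and one 4 times larger, no filter, a filter on the mean, quantile normalization, equal column totals, fits of the compared groups alone, a replicate block, no trend, single samples left out, and the D19 assembloid sets apart or as a single group. Genes for ribosomal proteins, pseudogenes, Y-linked genes and Xist were left out as an alternative chosen after seeing the data. Resemblance of cultures to kidney stages was given as a correlation across genes with no test.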

Results

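Bulk RNA-seq values were available for 34 mouse samples in 17 groups of 2. Kidneys taken at embryonic stages E12.5 and E15.5 and at postnatal days (P) 0, 9 and 45 made 5 groups. Explants, which are E12.5 kidneys kept in culture, made 7 groups: day (D) 7 in 10% fetal bovine serum (FBS), D17 in the medium called v0, D3, D7, D13 and D19 in the medium v1, and D19 in the medium v2. Kidney progenitor assembloids (mKPA), built from progenitor cells expanded in culture, made 5 groups in v2: D3, D7, D13 and 2 sets at D19 that the labels keep apart as r1 and r2. The labels call v0, v1 and v2 stage-based, so the medium may change with the day in comparisons between days. The depth implied by the smallest value step was 15243510 to 28457465 steps per library, except 7772154 in D19 v2 explant replicate 2. Log2 fold changes ± SE from limma follow gene names in parentheses, and rose, fell, higher and lower are used of genes past both thresholds. Adjusted p of a list is from camera with a preset correlation, with the value for an estimated correlation beside it where the list passed. Lists not named in a comparison did not pass there, and counts adjusted over the list alone equalled those over all genes unless given. No label says that the 2 samples of a group came from separate animals or cultures. The p-values thus measure only the spread between samples within groups. The fit pools that spread over all 17 groups, so it is not that of the compared groups alone. The kidneys were wild type and the cultures carried the Hoxb7-venus reporter, so genotype and culture cannot be separated in comparisons between them.

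The kidneys at P0 and E12.5 give the change over embryonic development against which the cultures can be read. All 20 proximal tubule genes rose (adjusted p = 2.89e-22, and adjusted p = 0.00174 with an estimated correlation). Slc34a1, the phosphate cotransporter of the brush border (ENSMUSG00000021490.12, chromosome 13, 55546000 to 55563405), was at the lowest step in both E12.5 libraries and at 678 ± 17.9 (SD, n = 2) at P0, at least 4450-fold higher with 3 steps per library as the floor. Mep1a (8.21 ± 0.30, at least 1960-fold), a brush-border protease, Pdzk1 (8.10), a scaffold for brush-border transporters, and Slc22a6 (7.74, at least 1420-fold), an organic anion transporter, rose with it. In the loop of Henle list 9 of 10 genes rose, among them the salt cotransporter Slc12a1 (8.73 ± 0.48, at least 2890-fold) and uromodulin Umod (6.80) (adjusted p = 1.14e-08, and adjusted p = 0.0104 with an estimated correlation). Of the distal convoluted and connecting tubule genes 8 of 10 rose, led by the salt cotransporter Slc12a3 (6.92) (adjusted p = 3.44e-07, and adjusted p = 0.00236 with an estimated correlation). Of the principal cell genes 11 of 12 rose, led by the water channel Aqp2 (8.58 ± 0.27) and by Aqp3 (5.69) (adjusted p = 2.62e-10, and adjusted p = 0.00279 with an estimated correlation). Aqp2 (ENSMUSG00000023013.6, chromosome 15, 99476936 to 99482428) stood at 393 ± 94.1 (SD, n = 2) at P0, at least 2580-fold above the E12.5 floor. Fatty acid oxidation genes rose in 10 of 12 cases, such as the dehydrogenase Acadm (2.82) and Ehhadh (2.22) (adjusted p = 6.07e-08, and adjusted p = 0.00737 with an estimated correlation).

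Other lists passed with the preset correlation alone. Podocyte genes rose in 9 of 14 cases (adjusted p = 9.65e-07, but adjusted p = 0.184 with an estimated correlation). Of the intercalated cell genes 10 of 11 rose, among them the proton pump subunit Atp6v1b1 (5.84), and 1 fell (adjusted p = 3.93e-06, but adjusted p = 0.0745 with an estimated correlation). The early nephron list had 5 of 10 genes higher (adjusted p = 0.0176, but adjusted p = 0.344 with an estimated correlation), and urothelium had 4 of 9 (adjusted p = 0.01, but adjusted p = 0.282 with an estimated correlation). The renin, pericyte and smooth muscle list had 5 of 9 higher (adjusted p = 0.0352, but adjusted p = 0.282 with an estimated correlation), led by renin itself, Ren1 (6.75 ± 0.39). Hypoxia and glycolysis genes rose in 5 of 11 cases, led by Ndrg1 (4.40) (adjusted p = 6.57e-04, but adjusted p = 0.184 with an estimated correlation). Tubular injury genes rose in 6 of 11, led by Spp1 (6.76) and the chaperone Clu (3.94) (adjusted p = 0.0247, but adjusted p = 0.282 with an estimated correlation). Embryonic stroma fell in 6 of 10 genes, led by the retinoic acid binding protein Crabp1 (−4.96), while Penk (4.25), which encodes proenkephalin, rose (adjusted p = 0.00208, but adjusted p = 0.0522 with an estimated correlation). Neuron genes fell in 9 of 10 cases (adjusted p = 7.88e-04, but adjusted p = 0.264 with an estimated correlation). Skeletal muscle genes fell in 6 of 8 (adjusted p = 0.00882, but adjusted p = 0.282 with an estimated correlation). The mean log2 level of that list was 2.555 ± 1.21 at E12.5 and 1.046 ± 0.142 at P0 (SD, n = 2 each). The 2 E12.5 libraries thus differed widely, and the size of this fall is uncertain. Adrenal gland genes fell in 3 of 4 (adjusted p = 0.0149, but adjusted p = 0.237 with an estimated correlation). Among them were the neurofilament Nefm (−5.23), the muscle filament Des (−1.85) and Dbh (−5.01, at least 217-fold), which makes noradrenaline. The mean log2 level of the adrenal list was 3.371 at E12.5 and 0.754 already at E15.5. Whether the neuron, muscle and adrenal transcripts of the E12.5 libraries came from kidney cells was not tested. None of the 12 cell cycle genes passed both thresholds, although the list lay lower (adjusted p = 0.00124, but adjusted p = 0.237 with an estimated correlation). The embryonic globins Hbb-y (−9.996), Hba-x (−7.48 ± 0.19) and Hbb-bh1 (−5.39) fell, with Hbb-bh1 at least 283-fold below its E12.5 level by the same floor. Chromogranin B Chgb (−5.85) and the potassium leak channel Kcnk9 (−5.10) fell as well. Globin genes are near-identical in sequence, and their separate values are uncertain. In all, 3748 of 19264 genes passed, 2437 higher and 1311 lower at P0. With quantile normalization, which shifted the median of all genes to −0.11, the split was 2020 higher and 1755 lower.

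Between P0 and P45 the comparison covers postnatal maturation. Proximal tubule genes rose in 17 of 20 cases (adjusted p = 6.24e-11, and adjusted p = 0.0127 with an estimated correlation), led by the androgen-regulated Kap (7.08 ± 0.32) and the lactate transporter Slc5a12 (5.81). Kap was 6.21 without P0 replicate 1 and 7.96 without P0 replicate 2. Xist, a transcript of female cells chosen after its values were seen, stood at 0.0429 and 340.3 in these replicates. It stood at 0.531 and 0.0698 in the P45 libraries, so the share of female cells may differ between the stages. Within P0, however, Kap was higher in replicate 2, the library with Xist. That is the reverse of lower values of an androgen-regulated gene with female cells. Distal tubule genes rose in 8 of 10, led by kallikrein Klk1 (6.64) and the calcium-binding Pvalb (4.15) (adjusted p = 2.72e-05, and adjusted p = 0.00901 with an estimated correlation). Fatty acid oxidation genes rose in 11 of 12 cases, including the hydroxylases Cyp4a14 (8.47 ± 0.18) and Cyp4a10 (5.09) (adjusted p = 7.82e-10, and adjusted p = 0.00901 with an estimated correlation). Egf (8.94 ± 0.23), made in the distal nephron, led the loop of Henle list, in which 9 of 10 rose (adjusted p = 6.22e-05, but adjusted p = 0.0624 with an estimated correlation). The tyrosine-catabolic Hpd (7.67 ± 0.16) was at the lowest step at P0 and at least 1400-fold higher at P45. Angptl7 (7.50) and the folate-releasing Folh1 (6.76) completed the largest rises.

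Ureteric tip genes fell in 8 of 8 cases, led by the receptor Ret (−4.25) and its target Etv4 (−3.92) (adjusted p = 5.12e-06, and adjusted p = 0.0208 with an estimated correlation). The cell cycle list fell in 12 of 12, led by Bub1 (−3.13) and Kif11 (−2.85) (adjusted p = 7.82e-10, and adjusted p = 0.0208 with an estimated correlation). Embryonic stroma fell in 8 of 10 genes, led by Aldh1a2 (−4.90), which makes retinoic acid (adjusted p = 1.55e-05, and adjusted p = 0.00901 with an estimated correlation). Cartilage genes fell in 4 of 6, led by Col2a1 (−4.99) (adjusted p = 0.00327, and adjusted p = 0.0208 with an estimated correlation). Six2 (−6.17 ± 0.25), which maintains nephron progenitors (ENSMUSG00000024134.12, chromosome 17, 85991705 to 85995702), fell from 74.4 ± 16.8 (SD, n = 2) to the lowest step, at least 355-fold lower. The rest of its list had 8 of 12 members lower in total (adjusted p = 1.92e-04, but adjusted p = 0.153 with an estimated correlation), including Eya1 (−5.45, at least 212-fold). The fetal growth genes H19 (−8.22 ± 0.13) and Igf2 (−7.18 ± 0.15), the fetal plasma protein Afp (−6.70) and the fibrillin Fbn2 (−6.09) fell. Matrix genes fell in 8 of 12 cases, led by Col1a1 (−2.63) (adjusted p = 0.00151, but adjusted p = 0.341 with an estimated correlation). Early nephron genes fell in 8 of 10 (adjusted p = 2.32e-04, but adjusted p = 0.188 with an estimated correlation). Intercalated cell genes rose in 9 of 11 (adjusted p = 1.08e-04, but adjusted p = 0.126 with an estimated correlation), led by the anion exchanger Slc26a4 (5.06). Sterol synthesis fell in 2 of 12 (adjusted p = 7.95e-04, but adjusted p = 0.341 with an estimated correlation). Of 5297 genes past both thresholds, 2635 rose and 2662 fell. When columns were rescaled to equal totals, undoing the deposited scaling, the median of all genes moved from −0.01 to −0.50 and the split became 1211 higher and 5269 lower. Because that shift enters every gene, fatty acid oxidation then had 7 members higher, intercalated cells 6, and sterol synthesis 10 lower. Mitochondrial transcripts made up 19.96 and 21.77% of the 2 P45 columns.

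**Figure D1:**
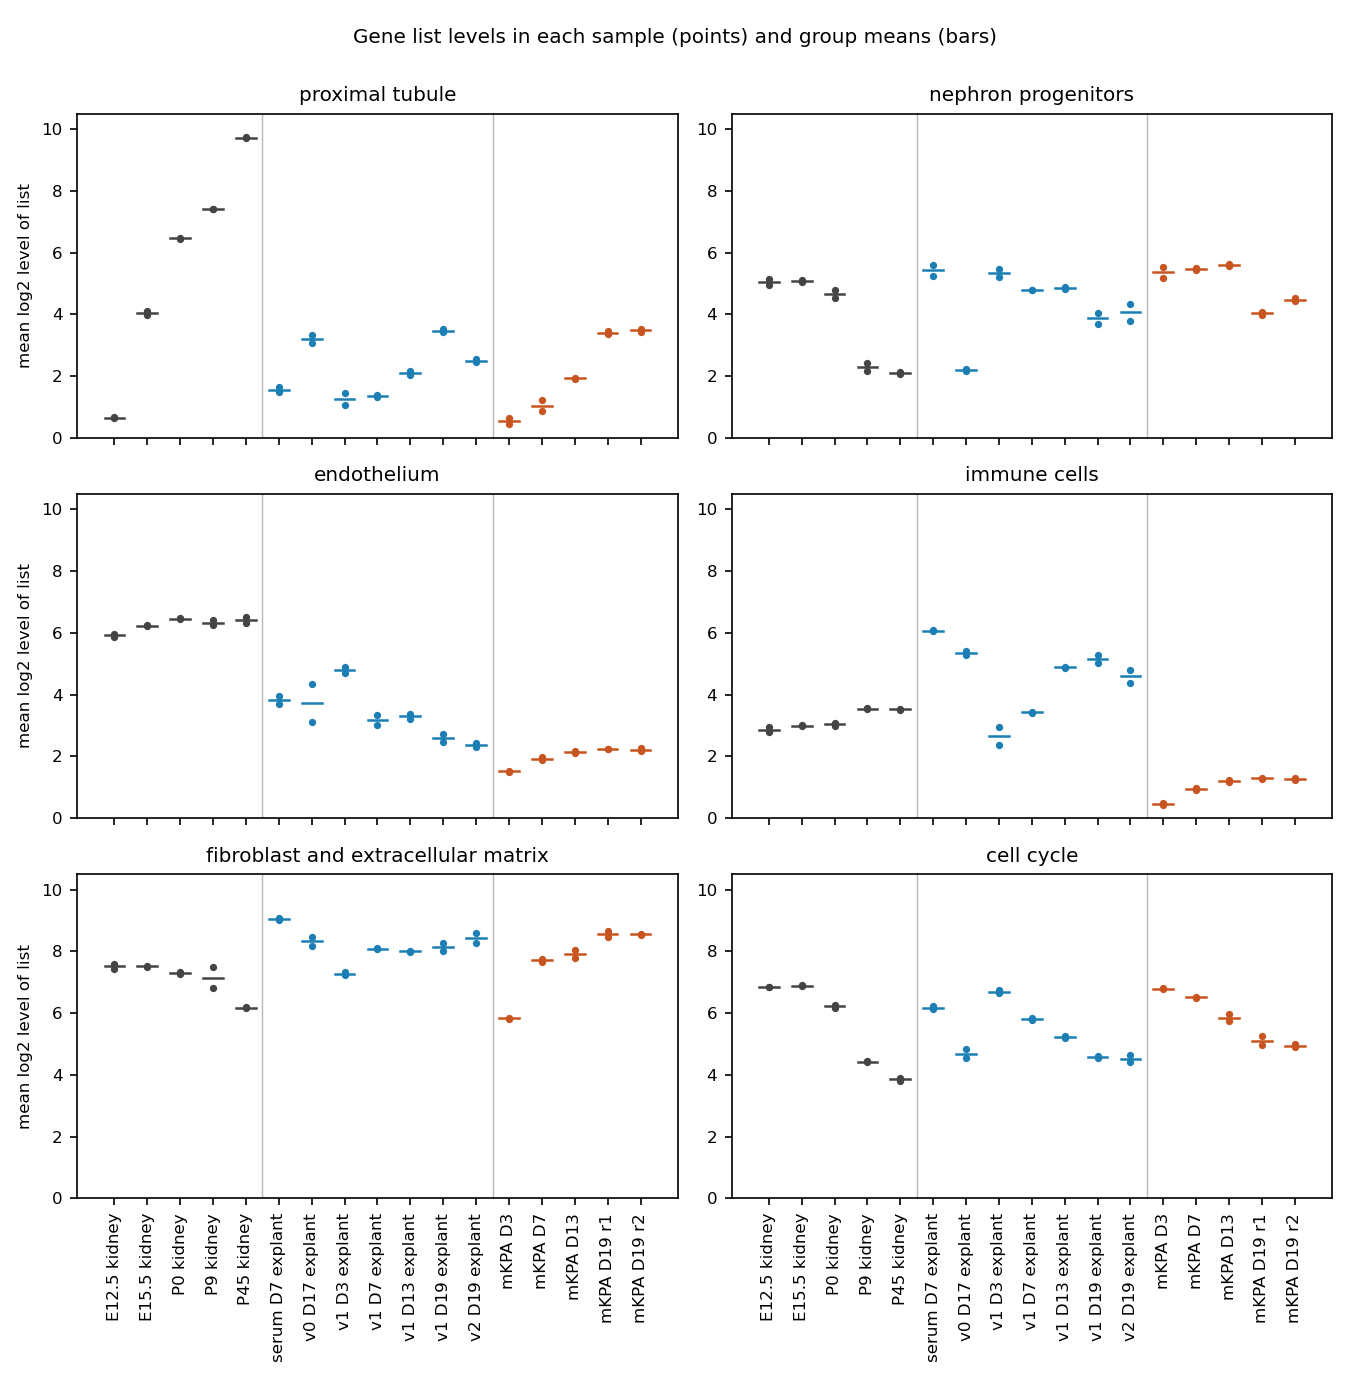
Mean log2(value + pseudocount) over the members of 6 gene lists in each of the 34 libraries (points), with the mean of each group of 2 as a bar, for kidneys (grey), explants (blue) and assembloids (orange). Proximal tubule genes lay at 0.653 at E12.5 and 9.72 at P45.

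D19 was compared with D3 in v1 explants. Proximal tubule genes rose in 15 of 20 cases (adjusted p = 1.84e-10, and adjusted p = 0.0169 with an estimated correlation), such as the gluconeogenic Fbp1 (4.62) and the fatty acid carrier Slc27a2 (4.46). All 12 immune genes rose, led by Cd74 (5.65 ± 0.27), which chaperones antigen-presenting molecules, and by the complement genes C1qa (2.95) and C1qc (2.71) (adjusted p = 2.64e-09, and adjusted p = 0.0169 with an estimated correlation). Fatty acid oxidation rose in 9 of 12 genes (adjusted p = 4.29e-08, and adjusted p = 0.0143 with an estimated correlation). Immediate early genes rose in 8 of 10, led by Fos (3.42) and Junb (3.19) (adjusted p = 3.45e-07, and adjusted p = 0.0175 with an estimated correlation). All 12 cell cycle genes fell, led by Bub1 (−2.60) (adjusted p = 4.51e-14, and adjusted p = 0.0143 with an estimated correlation). Ureteric tip genes fell in 7 of 8, led by Adamts18 (−3.15) (adjusted p = 1.41e-06, and adjusted p = 0.02 with an estimated correlation). The largest single rises were those of complement C3 (6.38 ± 0.37), the diamine oxidase Aoc1 (6.17 ± 0.24), the sugar transporter Slc5a10 (6.01), the liver-type pyruvate kinase Pklr (5.93), the small proline-rich Sprr2f (5.93) and osteopontin Spp1 (5.80). Sprr2f belongs to a family of near-identical genes, and its value is uncertain. Without D3 replicate 1 or 2, Pklr was 6.65 or 5.21, and Spp1 6.72 or 4.89.

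Endothelial genes fell in 9 of 12 cases and 1 rose (adjusted p = 2.40e-06, but adjusted p = 0.113 with an estimated correlation). Pecam1 (−5.10 ± 0.33) (ENSMUSG00000020717.20, chromosome 11, 106545043 to 106641454), an adhesion molecule between endothelial cells, fell from 77.3 ± 11 to 1.33 ± 0.393 (SD, n = 2 each). The receptor Tie1 (−4.52 ± 0.25), Mmrn2 (−4.09) and the transcription factor Sox18 (−4.02) fell with it. So did Cyp26b1 (−4.41 ± 0.16), which degrades retinoic acid, and Cntnap5b (−4.40). Sterol synthesis genes fell in 6 of 12 cases (adjusted p = 3.01e-09, but adjusted p = 0.0726 with an estimated correlation). Nephron progenitor genes fell in 6 of 12, led by Meox2 (−3.41) (adjusted p = 2.90e-05, but adjusted p = 0.113 with an estimated correlation). Erythroid genes fell in 4 of 9, led by Hba-a1 (−3.36, at least 73.7-fold) (adjusted p = 0.00107, but adjusted p = 0.191 with an estimated correlation). Other lists rose with the preset correlation alone. Podocyte genes rose in 7 of 14, led by the glomerular collagen Col4a4 (3.95) (adjusted p = 0.00193, but adjusted p = 0.328 with an estimated correlation). Loop of Henle genes rose in 7 of 10, led by Umod (3.87) (adjusted p = 8.26e-04, but adjusted p = 0.113 with an estimated correlation), and intercalated cell genes in 5 of 11, led by Foxi1 (2.60) (adjusted p = 0.00409, but adjusted p = 0.223 with an estimated correlation). Tubular injury had 6 of 11 higher (adjusted p = 1.72e-05, but adjusted p = 0.067 with an estimated correlation) and hypoxia 5 of 11 (adjusted p = 0.0045, but adjusted p = 0.223 with an estimated correlation). Matrix had 4 of 12 higher and 1 lower (adjusted p = 0.00409, but adjusted p = 0.328 with an estimated correlation). Aqp2 (4.46 ± 0.27) rose to 34.2 ± 4.22 (SD, n = 2), while its principal cell list had 3 of 12 higher (adjusted p = 0.302). Altogether 3163 genes passed, 2014 higher and 1149 lower at D19.

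The comparison of v1 with serum at D7 sets a stage-based medium against serum on the same day. Immune genes fell in 11 of 12 cases in v1, led by lysozyme Lyz2 (−4.46 ± 0.34), Fcer1g (−3.61) and C1qb (−3.27) (adjusted p = 4.36e-11, and adjusted p = 0.0217 with an estimated correlation). This was the only list past the threshold with both correlations. Cyp26b1 (7.30 ± 0.16), which clears retinoic acid (ENSMUSG00000063415.13, chromosome 6, 84548396 to 84570890), stood at 803 ± 84.5 in v1 and 4.15 ± 0.693 in serum (SD, n = 2 each). Lrat (4.70 ± 0.25), which esterifies retinol for storage, Cntnap5b (5.46), somatostatin Sst (4.57) and the collagen Col6a6 (4.38) were higher too. Lower in v1 were the matrix protein Ltbp2 (−5.94 ± 0.31), osteopontin Spp1 (−5.69), the macrophage elastase Mmp12 (−5.38) and the lysosomal protease Ctss (−4.58). The ribosomal protein Rpl29 (6.08 ± 1.59) was higher and Rps3a3 (−4.88) lower. Both share sequence with near-identical copies and switched between replicates elsewhere in the series, so their values are uncertain. Here they split by group, with Rpl29 at 1.12 and 2.04 in serum and 156 and 180 in v1. Rps3a3 stood at 123 and 162 in serum and at 3.87 in both v1 libraries. Strain is not given per sample, so a difference in animals between the 2 groups remains open.

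Embryonic stroma genes were higher in 6 of 10 cases, led by Penk (3.42) and the growth regulator Dlk1 (1.84) (adjusted p = 0.00153, but adjusted p = 0.0608 with an estimated correlation). Urothelial genes were higher in 5 of 9, led by the uroplakins Upk3a (3.09) and Upk3b (2.20) (adjusted p = 0.0133, but adjusted p = 0.739 with an estimated correlation). Matrix genes were lower in 5 of 12, led by Tnc (−2.90) and Postn (−2.20) (adjusted p = 0.00785, but adjusted p = 0.739 with an estimated correlation). Immediate early genes were lower in 4 of 10, led by Fos (−2.51) (adjusted p = 0.0139, but adjusted p = 0.64 with an estimated correlation). Sterol synthesis lay higher as a list with 0 of 12 members past both thresholds (adjusted p = 0.0153, but adjusted p = 0.739 with an estimated correlation). Proximal tubule genes went both ways, 3 higher and 4 lower, led by the endocytic receptor Lrp2 (−2.15) (adjusted p = 0.516). Podocytes had 5 of 14 genes lower and 1 higher (adjusted p = 0.0859), and endothelium 3 of 12 lower, led by the receptor Flt1 (−3.35), and 1 higher, Emcn (1.76) (adjusted p = 0.208). In total 2183 genes passed, 1101 higher and 1082 lower in v1. With columns at equal totals the split was 1387 higher and 897 lower.

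D19 v1 and D17 v0 explants differ in day as well as medium, so the 2 cannot be separated. Nephron progenitor genes were higher in v1 in 8 of 12 cases (adjusted p = 5.44e-08, but adjusted p = 0.192 with an estimated correlation). Six2 (4.29 ± 0.25) stood at 35.7 ± 9.63 in v1 and 0.900 ± 0.415 in v0 (SD, n = 2 each), and Eya1 (3.54 ± 0.24), its partner in progenitor cells, was higher too. The transcription factor Zbtb16 (5.00 ± 0.24), the sugar transporter Slc5a10 (3.90), the growth factor Areg (3.30) and Pklr (2.995) led the other rises. The retinoic acid hydroxylases Cyp26b1 (−4.54 ± 0.16) and Cyp26a1 (−3.95 ± 0.28) were lower in v1, as were the secreted Wnt antagonist Sfrp5 (−4.58 ± 0.35), the receptor Npffr2 (−3.99), Tex15 (−3.67) and the oxygenase Fmo5 (−3.64). Urothelial genes were lower in 6 of 9 cases, with Upk3a (−1.88) and Upk2 (−1.70) (adjusted p = 0.00135, but adjusted p = 0.274 with an estimated correlation). Endothelial genes were lower in 5 of 12, led by Tie1 (−3.44) (adjusted p = 2.49e-05, but adjusted p = 0.259 with an estimated correlation). Embryonic stroma was higher in 4 of 10, led by Crabp1 (2.20) (adjusted p = 0.0214, but adjusted p = 0.232 with an estimated correlation). Hypoxia and glycolysis genes were higher in 2 of 11, led by Ndrg1 (1.84) (adjusted p = 1.36e-04, but adjusted p = 0.232 with an estimated correlation). No member of the sterol synthesis list passed both thresholds though the list lay higher (adjusted p = 9.79e-07, but adjusted p = 0.232 with an estimated correlation), and none of the podocyte list, which lay lower (adjusted p = 0.0302, but adjusted p = 0.762 with an estimated correlation). Immune genes gave 0 higher and 0 lower of 12 (adjusted p = 0.25). With an estimated correlation camera called 0 lists, with 5 at an unadjusted p under 0.05. Of 1049 genes that passed, 506 were higher and 543 lower in v1. The split was 405 and 652 with equal totals, 263 and 253 with 4 times the pseudocount and 401 and 285 with a filter on the mean, so the larger direction depended on the processing.

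At D19 the v2 and v1 explants differ in medium by their labels. Ren1 (7.39 ± 0.39), which encodes renin (ENSMUSG00000070645.6, chromosome 1, 133278248 to 133288063), stood at 271 ± 87.3 in v2 and 0.661 ± 0.496 in v1 (SD, n = 2 each). Akr1b7 (2.61 ± 0.25), another product of renin cells, was higher with it, and Cspg4 (−1.47), a pericyte proteoglycan, was lower (2 higher and 1 lower of 9; adjusted p = 0.0142, but adjusted p = 0.353 with an estimated correlation). The water channel Aqp2 (2.86 ± 0.27) led the principal cells, with 3 of 12 higher (adjusted p = 5.18e-07, and adjusted p = 0.0272 with an estimated correlation). Proximal tubule genes were lower in 7 of 20 cases, led by Slc34a1 (−3.10 ± 0.26), Slc27a2 (−1.74) and Ttc36 (−1.73) (adjusted p = 9.69e-11, and adjusted p = 0.0272 with an estimated correlation). Other genes higher in v2 were the lectin Reg3g (3.27), the BMP antagonist Grem1 (3.14 ± 0.24), the immediate early gene Fosb (3.04 ± 0.37) and the collagen Col6a5 (2.80). Fosb was 2.39 without v1 replicate 1 and 3.68 without v1 replicate 2, and its adjusted p was 0.128 with only these 2 groups in the fit. Lower were Hsd3b4 (−2.66), Col6a4 (−2.49), Sytl2 (−2.43), the antigen-presenting H2-Eb1 (−2.37) and the lactate transporter Slc5a8 (−2.33).

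Immediate early genes were higher in 2 of 10 cases, Fosb and Fos (2.03) (adjusted p = 5.00e-04, but adjusted p = 0.172 with an estimated correlation). Podocyte genes were lower in 3 of 14, with Clic5 (−1.20) and Tcf21 (−1.17) (adjusted p = 0.00439, but adjusted p = 0.414 with an estimated correlation). Fatty acid oxidation genes were lower in 2 of 12 (adjusted p = 0.00228, but adjusted p = 0.172 with an estimated correlation). Immune genes were lower in 2 of 12, Cx3cr1 (−1.95) and Cd74 (−1.73) (adjusted p = 0.0141, but adjusted p = 0.353 with an estimated correlation). The early nephron list had 1 of 10 members lower, and 3 adjusted over the list alone (adjusted p = 0.0141, but adjusted p = 0.414 with an estimated correlation). The matrix list had 0 of 12 higher, and 1 adjusted over the list alone (adjusted p = 0.00496, but adjusted p = 0.414 with an estimated correlation). Ureteric tip (adjusted p = 0.0257, but adjusted p = 0.353 with an estimated correlation) and sterol synthesis (adjusted p = 0.00634, but adjusted p = 0.414 with an estimated correlation) lay higher with no member past both thresholds in that direction. Cell cycle genes gave 0 higher and 0 lower of 12 (adjusted p = 0.879). In all 548 genes passed, 218 higher and 330 lower in v2. D19 v2 explant replicate 2 was the shallowest library, held 6.39% of its signal on pseudogenes (4.17 to 6.26% in the others) and had 30 genes at least 8-fold above every other library. With quantile normalization the split was near even, 258 higher and 270 lower. Without v2 replicate 2, 490 genes passed, 229 higher and 261 lower and 377 of them shared, and the proximal tubule list had 6 members lower.

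For the assembloids, D19 was compared with D3, with the mean of r1 and r2 as the D19 value. The Y-linked gene Ddx3y, chosen after its values were seen, stood at 4.94 to 10.2 in the 6 libraries of D3 to D13 and at 1 step in all 4 of D19, so day and cell source may differ together here. Proximal tubule genes rose in 17 of 20 cases (adjusted p = 3.56e-11, and adjusted p = 0.0465 with an estimated correlation). This was the only list past the threshold with both correlations. Among them were Slc22a6 (5.44 ± 0.24), the water channel Aqp1 (5.11), and Slc34a1 (5.13 ± 0.22), which reached 40.8 ± 3.23 (SD, n = 4). Spp1 (7.29 ± 0.43), C3 (6.95 ± 0.32), the organic anion pump Abcc2 (6.84), Aqp2 (6.64 ± 0.23) and Ren1 (6.32 ± 0.34) were among the largest rises. The principal cell list that holds Aqp2 did not pass, and its median log2 change was −0.846. Without D3 replicate 1 or 2, Spp1 was 8.12 or 6.45. Loop of Henle genes rose in 8 of 10, with Kcnj1 (4.03), a potassium channel at the lowest step at D3, at least 102-fold higher (adjusted p = 1.63e-06, but adjusted p = 0.0565 with an estimated correlation). Matrix genes rose in 11 of 12, led by the smooth muscle Tagln (4.77) and the proteoglycan Dcn (4.42) (adjusted p = 3.49e-10, but adjusted p = 0.0654 with an estimated correlation). The renin, pericyte and smooth muscle list rose in 5 of 9 with 1 lower, and included the myosin Myh11 (5.78) (adjusted p = 5.74e-04, but adjusted p = 0.0896 with an estimated correlation). Podocyte genes rose in 8 of 14, with Podxl (4.59) (adjusted p = 2.04e-05, but adjusted p = 0.203 with an estimated correlation). Intercalated cell genes rose in 8 of 11, led by Foxi1 (3.84) (adjusted p = 2.62e-05, but adjusted p = 0.0885 with an estimated correlation).

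The small proline-rich Sprr1a (−7.20 ± 0.32), the pore-forming Gsdmc2 (−6.69 ± 0.26) and Gsdmc3 (−6.67), the protease Ctse (−6.05 ± 0.21), Cyp26b1 (−6.86 ± 0.14) and the cartilage collagen Col2a1 (−4.95 ± 0.18) fell most. The Sprr and Gsdmc families hold near-identical copies, so their separate values are uncertain. Cell cycle genes fell in 11 of 12, led by Cenpe (−2.43) (adjusted p = 3.36e-10, but adjusted p = 0.0524 with an estimated correlation). Nephron progenitor genes fell in 7 of 12 and rose in 2, with Meox1 (−4.18) and Meox2 (−3.77) lowest (adjusted p = 0.00691, but adjusted p = 0.295 with an estimated correlation). Ureteric tip genes fell in 5 of 8, led by Ret (−2.99) (adjusted p = 5.74e-04, but adjusted p = 0.0885 with an estimated correlation). Immediate early genes rose in 8 of 10 (adjusted p = 1.41e-04, but adjusted p = 0.0849 with an estimated correlation). Hypoxia genes rose in 7 of 11, led by Ndrg1 (5.23) (adjusted p = 1.80e-05, but adjusted p = 0.0885 with an estimated correlation). Fatty acid oxidation genes rose in 6 of 12 (adjusted p = 6.39e-05, but adjusted p = 0.0642 with an estimated correlation). Tubular injury genes rose in 5 of 11, with Vcam1 (4.53) (adjusted p = 0.0042, but adjusted p = 0.203 with an estimated correlation). Endothelium rose in 5 of 12, with Kdr (2.22) and Cdh5 (1.90) (adjusted p = 0.0353, but adjusted p = 0.431 with an estimated correlation). Sterol synthesis lay lower with no member past both thresholds (adjusted p = 0.0021, but adjusted p = 0.307 with an estimated correlation). Immune genes rose in 3 of 12, with Cd74 (4.38) (adjusted p = 0.0582). Of 3343 genes that passed, 2101 rose and 1242 fell.

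D19 assembloids and D19 v2 explants share day and medium and differ in origin. Immune genes were lower in assembloids in 10 of 12 cases (adjusted p = 1.20e-24, and adjusted p = 3.31e-04 with an estimated correlation). Lyz2 (−7.03 ± 0.29), Stab1 (−6.23 ± 0.16) and Mrc1 (−6.06 ± 0.19), genes of macrophages, were lower by the widest margins. C1qa (−4.92 ± 0.20) (ENSMUSG00000036887.6, chromosome 4, 136623228 to 136626114) stood at 30.4 ± 8.16 (SD, n = 2) in explants and at the lowest step in all 4 assembloid libraries, at least 181-fold lower. Urothelial genes were lower in 7 of 9 cases, and in 8 adjusted over the list alone, with Upk1b (−4.12 ± 0.33) and Krt15 (−2.90) (adjusted p = 4.46e-09, and adjusted p = 0.0385 with an estimated correlation). Immediate early genes were lower in 6 of 10, led by Fosb (−3.66 ± 0.32) and Fos (−2.41) (adjusted p = 9.77e-08, and adjusted p = 0.0273 with an estimated correlation). Ly6d (−4.96) and Col6a5 (−4.94) were lower as well. Genes higher in assembloids were the photoreceptor cadherin Cdhr1 (3.46 ± 0.35) and the gastric lipase Lipf (3.39 ± 0.21). The others in that group of 6 were Rpl29 (4.52 ± 1.38), Ahcy (3.64 ± 0.72), Rpl34 (3.29 ± 0.16) and AI506816 (3.48 ± 0.25), which are uncertain. Rpl29, Ahcy and Rpl34 share sequence with near-identical copies, and AI506816 also differed among kidneys, at 6.94 ± 0.519 at E12.5 and 113 ± 2.48 at E15.5 (SD, n = 2 each). Rpl29 was 2.37 without v2 explant replicate 1, with adjusted p = 0.331, and 6.67 without replicate 2. Its adjusted p was 0.14 with only the compared groups in the fit, 0.0565 with r1 alone and 0.0521 with r2 alone.

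Proximal tubule genes were higher in assembloids in 7 of 20 cases, led by Kap (3.24) and Slc34a1 (2.61) (adjusted p = 6.97e-07, but adjusted p = 0.0849 with an estimated correlation). Intercalated cell genes were higher in 6 of 11, led by Insrr (1.89) (adjusted p = 5.64e-05, but adjusted p = 0.152 with an estimated correlation), and in 3 without v2 explant replicate 2. Principal cells had 1 of 12 lower, the water channel Aqp4 (−4.03) (adjusted p = 0.00609, but adjusted p = 0.196 with an estimated correlation). The cell cycle list lay higher with 0 of 12 past both thresholds (adjusted p = 1.57e-05, but adjusted p = 0.152 with an estimated correlation), as did sterol synthesis (adjusted p = 0.0254, but adjusted p = 0.611 with an estimated correlation), and hypoxia had 1 of 11 higher (adjusted p = 0.00351, but adjusted p = 0.311 with an estimated correlation). Podocytes gave 0 higher and 0 lower of 14 (adjusted p = 0.616), and endothelium 1 of 12 lower (adjusted p = 0.309). Of the genes that passed, 1048 in all, 414 were higher and 634 lower in assembloids. Without v2 explant replicate 2, 986 passed and 813 of them were shared.

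**Figure D2:**
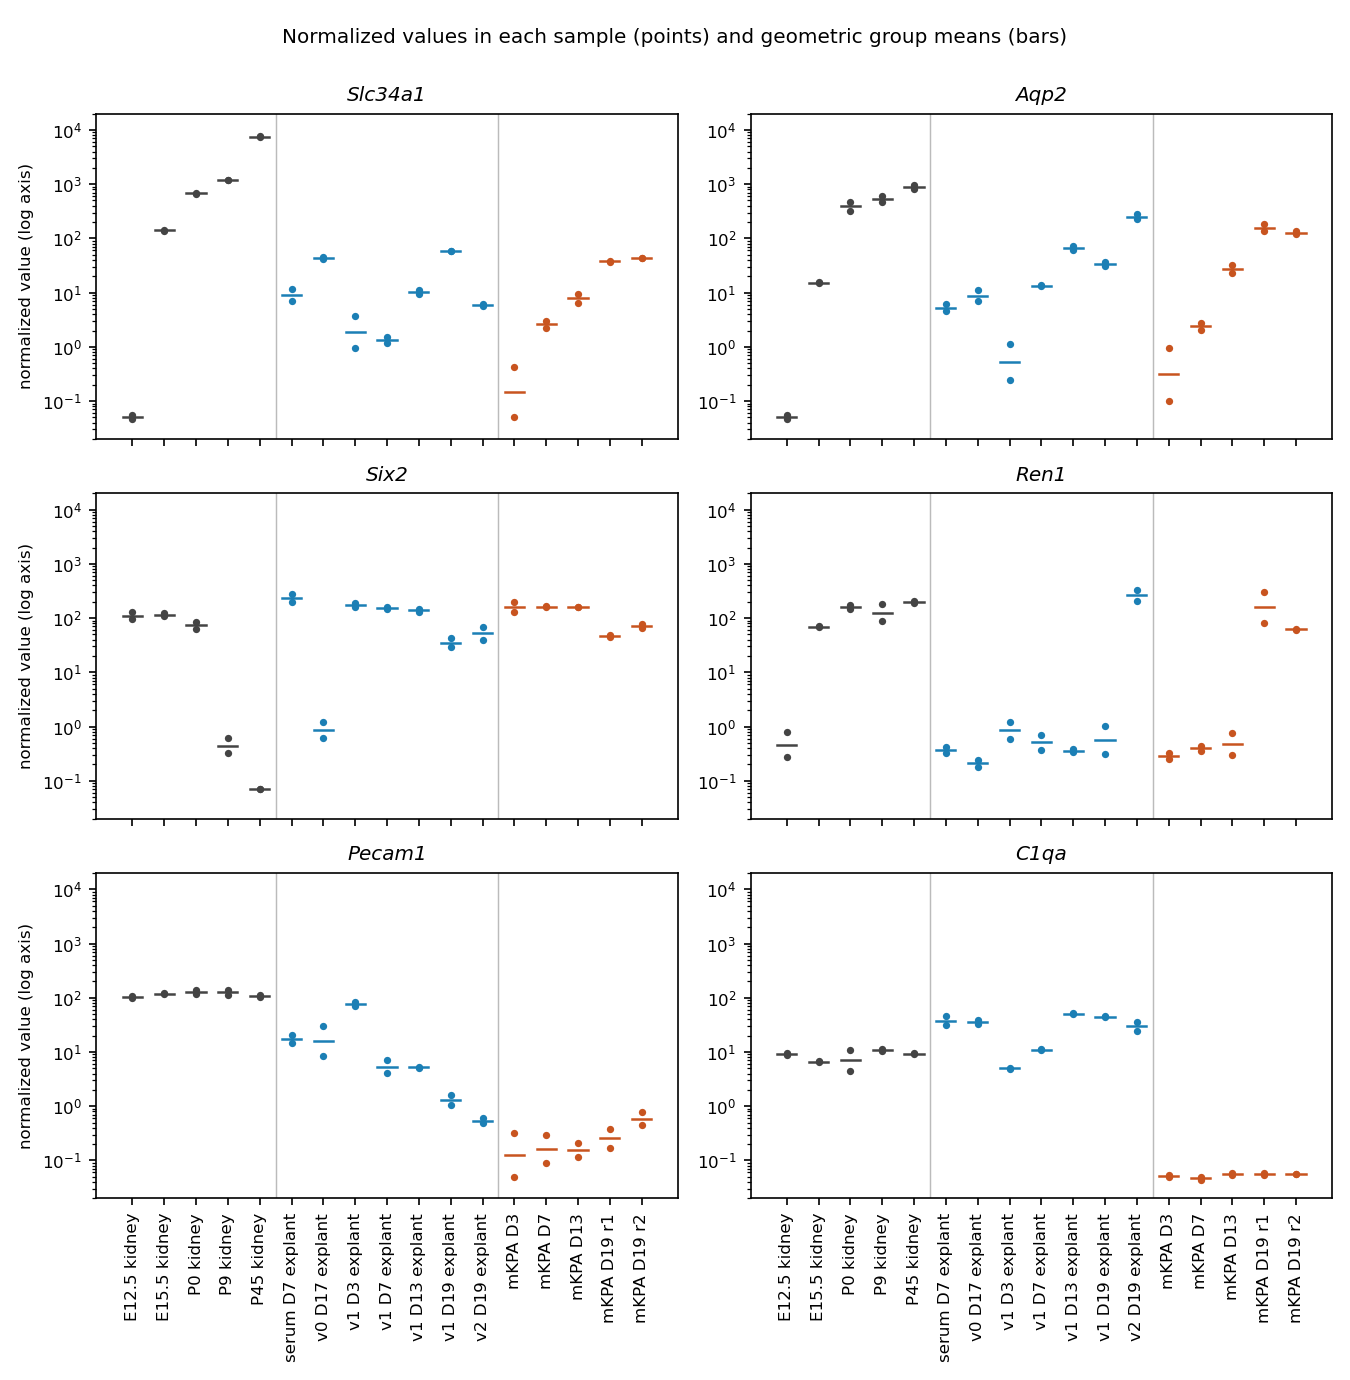
Deposited TMM-normalized values, on a log axis, of Slc34a1, Aqp2, Six2, Ren1, Pecam1 and C1qa in each of the 34 libraries (points), with the geometric mean of each group of 2 as a bar, for kidneys (grey), explants (blue) and assembloids (orange). Slc34a1 lay at the lowest step at E12.5 and at 7661 and 7360 in the 2 P45 libraries.

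The v2 explants at D19 were set against the newborn kidney. All 20 proximal tubule genes were lower in explants (adjusted p = 3.48e-20, and adjusted p = 0.00295 with an estimated correlation), led by Slc34a1 (−6.63 ± 0.26), the endocytic receptor Cubn (−6.20) and the inositol oxygenase Miox (−5.92). Loop of Henle genes were lower in 9 of 10, led by the tight junction Cldn19 (−5.12) (adjusted p = 1.01e-05, and adjusted p = 0.0462 with an estimated correlation). Distal tubule genes were lower in 7 of 10, led by Slc12a3 (−4.57) (adjusted p = 1.05e-05, and adjusted p = 0.00731 with an estimated correlation). Intercalated cell genes were lower in 10 of 11, with the proton pump subunit Atp6v1b1 (−3.50) and the anion exchanger Slc4a1 (−3.44) (adjusted p = 2.88e-06, and adjusted p = 0.0488 with an estimated correlation). Endothelial genes were lower in 11 of 12 cases (adjusted p = 2.78e-12, and adjusted p = 0.0293 with an estimated correlation). The capillary Plvap (−6.87 ± 0.59) was among the 6 largest falls, and Pecam1 (−6.43 ± 0.33) stood at 0.542 ± 0.0731 against 129 ± 14.2 at P0 (SD, n = 2 each). Adult globins fell furthest, with Hba-a1 (−10.44 ± 0.20), Hbb-bs (−10.41 ± 0.17), Hba-a2 (−9.16) and Hbb-bt (−7.58, at least 877-fold), and Hbb-bs at least 6130-fold lower (5 of 9 erythroid genes; adjusted p = 1.33e-06, and adjusted p = 0.0462 with an estimated correlation). Spp2 (−6.69) was lower too. All 12 cell cycle genes were lower, led by Birc5 (−2.02) (adjusted p = 6.38e-11, and adjusted p = 0.0215 with an estimated correlation).

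Immune genes were higher in explants in 8 of 12 cases and lower in 1, with Lyz2 (4.40 ± 0.34) and the lysosomal Cd68 (3.15) (adjusted p = 6.14e-06, and adjusted p = 0.0462 with an estimated correlation). Tubular injury genes were higher in 8 of 11, led by Lcn2 (3.39) and Krt20 (3.01) (adjusted p = 8.77e-06, and adjusted p = 0.0462 with an estimated correlation). Immediate early genes were higher in 9 of 10, led by Fosb (5.55 ± 0.37) and Fos (5.21) (adjusted p = 2.35e-10, and adjusted p = 0.00731 with an estimated correlation). The largest rises were C3 (7.02 ± 0.37), the glycoprotein Gpnmb (6.89 ± 0.40), the adhesion molecule Cntn1 (6.02), the stress cytokine Gdf15 (5.74 ± 0.21) and the protease inhibitor Serpina3n (5.51 ± 0.38), the last at least 313-fold higher. Matrix genes were higher in 7 of 12 and lower in 1, led by Lum (4.51) and Dcn (4.11) (adjusted p = 3.77e-04, but adjusted p = 0.244 with an estimated correlation). Sterol synthesis genes were higher in 4 of 12 (adjusted p = 2.28e-06, but adjusted p = 0.128 with an estimated correlation). Other lists were lower with the preset correlation alone. Ureteric tip had 4 of 8 lower, led by Wnt11 (−4.01) (adjusted p = 0.00226, but adjusted p = 0.123 with an estimated correlation), and hypoxia and glycolysis 6 of 11 (adjusted p = 0.0051, but adjusted p = 0.244 with an estimated correlation). Early nephron had 5 of 10 lower (adjusted p = 0.033, but adjusted p = 0.428 with an estimated correlation), and podocytes 3 of 14, with Rhpn1 (−2.89) (adjusted p = 0.0335, but adjusted p = 0.543 with an estimated correlation). Of 3119 genes past both thresholds 1379 were higher and 1740 lower in explants. Without v2 explant replicate 2 the count was 3140, with 2733 shared, and immune genes were 9 higher and 0 lower. Equal totals moved the median of all genes from −0.08 to −0.11. With quantile normalization the split was 1617 higher and 1503 lower, so which direction held more genes depended on the scaling.

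The D19 assembloids were set against the same newborn kidneys. Proximal tubule genes were lower in 17 of 20 cases (adjusted p = 1.01e-17, and adjusted p = 0.00576 with an estimated correlation), led by the amino acid transporter Slc7a13 (−4.99 ± 0.23), Cubn (−4.88) and Miox (−4.81). Loop of Henle was lower in 8 of 10, with Cldn19 (−3.48) and Umod (−2.82) (adjusted p = 4.30e-06, and adjusted p = 0.036 with an estimated correlation). Distal tubule genes were lower in 6 of 10, led by Klk1 (−3.44) (adjusted p = 2.22e-05, and adjusted p = 0.0141 with an estimated correlation). Principal cell genes were lower in 7 of 12, led by Aqp4 (−4.86) and the vasopressin receptor Avpr2 (−2.88) (adjusted p = 9.31e-05, and adjusted p = 0.0454 with an estimated correlation). All 12 endothelial genes were lower (adjusted p = 3.38e-15, and adjusted p = 0.0221 with an estimated correlation), led by Tie1 (−6.58 ± 0.22) and Pecam1 (−6.55 ± 0.28), which stood at 0.445 ± 0.254 (SD, n = 4). The apelin receptor Aplnr (−6.81 ± 0.37) was lower too. The adult globins Hba-a1 (−10.61 ± 0.17) and Hbb-bs (−10.44 ± 0.15) were at the lowest step in all 4 assembloid libraries, at least 9550-fold and 8440-fold lower, and Hba-a2 (−9.21, at least 3600-fold) and Hbb-bt (−7.61, at least 1210-fold) followed (adjusted p = 1.04e-07, and adjusted p = 0.036 with an estimated correlation). Cell cycle genes were lower in 11 of 12, led by Mki67 (−1.48) (adjusted p = 1.54e-09, and adjusted p = 0.03 with an estimated correlation).

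Immediate early genes were higher in 8 of 10, led by Fos (2.80) and Junb (2.76) (adjusted p = 9.42e-07, and adjusted p = 0.0281 with an estimated correlation). The largest rises were the retinaldehyde dehydrogenase Aldh1a1 (5.65 ± 0.37), C3 (5.23 ± 0.32), Cntn1 (5.22), Serpina3n (5.18 ± 0.33, at least 306-fold), the tenascin Tnxb (5.14 ± 0.17) and Gdf15 (5.08). Immune genes were lower in 9 of 12 and higher in 1, led by Cx3cr1 (−3.54, at least 65.9-fold) and C1qb (−3.51, at least 64.9-fold) (adjusted p = 2.63e-05, but adjusted p = 0.0521 with an estimated correlation). Further lists were lower with the preset correlation alone. Urothelium had 5 of 9 lower and 1 higher, led by Upk3a (−4.69, at least 151-fold) (adjusted p = 0.00196, but adjusted p = 0.172 with an estimated correlation). Intercalated cells had 7 of 11 lower (adjusted p = 0.00175, but adjusted p = 0.17 with an estimated correlation) and ureteric tip 2 of 8 (adjusted p = 0.00439, but adjusted p = 0.132 with an estimated correlation). Early nephron had 5 of 10 lower (adjusted p = 0.00279, but adjusted p = 0.232 with an estimated correlation). Podocytes had 7 of 14 lower and 1 higher (adjusted p = 0.00996, but adjusted p = 0.4 with an estimated correlation). Matrix genes were higher in 6 of 12, led by Lum (4.03) (adjusted p = 5.49e-06, but adjusted p = 0.118 with an estimated correlation). Sterol synthesis genes were higher in 4 of 12, led by Insig1 (1.85) (adjusted p = 1.54e-09, but adjusted p = 0.0515 with an estimated correlation). Tubular injury genes were higher in 4 of 11, led by Lcn2 (3.15) (adjusted p = 2.22e-05, but adjusted p = 0.0515 with an estimated correlation). Nephron progenitors had 2 higher and 3 lower of 12 (adjusted p = 0.488). Altogether 2396 genes passed, 1094 higher and 1302 lower in assembloids. With quantile normalization 1241 were higher and 1179 lower, so here too the larger direction depended on the scaling.

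The labels keep r1 and r2 apart at D19 without saying what they stand for. Only 32 genes differed, 12 higher and 20 lower in r2, with 1075 at an unadjusted p under 0.05. The dipeptidase Dpep1 (1.61 ± 0.22) led the genes higher in r2 and the cadherin Cdh13 (−2.24 ± 0.31) those lower. Cdh13 was −1.88 with adjusted p = 0.0539 without r1 replicate 2. Leaving out single libraries gave 6 to 37 genes: 37 without r1 replicate 1, 7 without r1 replicate 2, 6 without r2 replicate 1 and 17 without r2 replicate 2. With only these 2 groups in the fit limma called 0 genes, with 1873 at an unadjusted p under 0.05. The nephron progenitor list (adjusted p = 2.82e-07, but adjusted p = 0.0881 with an estimated correlation) and the early nephron list (adjusted p = 4.70e-07, but adjusted p = 0.0993 with an estimated correlation) lay higher in r2. So did ureteric tip (adjusted p = 8.29e-07, but adjusted p = 0.0881 with an estimated correlation) and intercalated cells (adjusted p = 8.41e-07, but adjusted p = 0.0881 with an estimated correlation). Distal tubule (adjusted p = 0.00199, but adjusted p = 0.0881 with an estimated correlation) and hypoxia (adjusted p = 0.0014, but adjusted p = 0.234 with an estimated correlation) lay higher too. Sterol synthesis (adjusted p = 1.42e-07, but adjusted p = 0.134 with an estimated correlation) and the renin list (adjusted p = 0.00201, but adjusted p = 0.181 with an estimated correlation) lay lower. Cell cycle (adjusted p = 0.00188, but adjusted p = 0.264 with an estimated correlation) and tubular injury (adjusted p = 0.00611, but adjusted p = 0.264 with an estimated correlation) lay lower as well. With an estimated correlation camera called 0 lists, with 7 at an unadjusted p under 0.05. Across these 10 lists the kallikrein Klk1 (1.30), the receptor Insrr (1.26) and Akr1b7 (−1.25) passed both thresholds as single genes, and each lost its call without single libraries, with either other pseudocount and with only these groups in the fit. Klk1 was 1.07, 1.52 and 0.82 without r1 replicate 1, r1 replicate 2 and r2 replicate 1, and Insrr 0.94 and 0.97 without r1 replicate 2 and r2 replicate 1. Akr1b7 was −0.86, −1.22 and −1.27 without r1 replicate 2, r2 replicate 1 and r2 replicate 2. With the pseudocount divided by 4 Klk1, Insrr and Akr1b7 were 1.96, 1.38 and −1.41 (adjusted p = 0.0728, 0.0563 and 0.149), and with 4 times the pseudocount 0.59, 0.94 and −0.86. Adjusted over the list alone, 1 early nephron gene was higher and 2 genes of the renin list were lower.

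The D3 to D19 change was then compared between assembloids and v1 explants, which also differ in medium, and the split in Ddx3y between D3 and D19 assembloids enters this comparison too. Endothelial genes moved up in assembloids relative to explants in 10 of 12 cases and down in 1 (adjusted p = 3.61e-13, and adjusted p = 0.0381 with an estimated correlation), with Pecam1 (5.39 ± 0.43), Cdh5 (4.94 ± 0.40) and Esam (4.30). The mean log2 level of the endothelial list was 1.511 in D3 and 2.229 in D19 assembloids. In D3 and D19 v1 explants it was 4.8 and 2.591, so the larger part of the difference reflects the fall in explants. The endothelial Sox7 (5.06 ± 0.38) and Cldn5 (4.76 ± 0.48) lay among the 6 largest upward differences, and Cldn5 was 4.09 without assembloid D3 replicate 1 and 5.43 without replicate 2. Matrix genes moved up in 11 of 12, led by Tnc (3.30) and Dcn (2.87) (adjusted p = 1.43e-13, and adjusted p = 0.0381 with an estimated correlation). Immune genes moved down in 10 of 12, led by C1qa (−2.95 ± 0.31) and C1qc (−2.71) (adjusted p = 3.24e-08, and adjusted p = 0.0381 with an estimated correlation). Both stood at the lowest step in every assembloid library of D3 and D19, so their differences reflect the rise in explants alone. Ren1 (6.54 ± 0.52) had the largest upward difference, and its list moved up in 6 of 9, with the potassium channel Kcnj8 (3.72) (adjusted p = 2.31e-05, but adjusted p = 0.0682 with an estimated correlation). Penk (4.60 ± 0.30) moved up, and Gsdmc3 (−11.15 ± 0.65), Gsdmc2 (−10.86 ± 0.40), Sprr1a (−7.51 ± 0.49), Ctse (−7.31 ± 0.32), Sprr2f (−6.20) and Sprr2a3 (−5.81) moved down. Urothelium moved down in 5 of 9, and in 7 adjusted over the list alone, led by Upk3a (−5.78), at the lowest step in D19 assembloids (adjusted p = 3.59e-05, but adjusted p = 0.112 with an estimated correlation). Erythroid genes moved up in 4 of 9 (adjusted p = 3.59e-05, but adjusted p = 0.112 with an estimated correlation). The mean log2 level of that list was 0.036 in D3 and 0.07 in D19 assembloids. It was 1.23 in D3 and 0.026 in D19 v1 explants, so the difference reflects the fall in explants. Loop of Henle moved up in 5 of 10, with Cldn19 (2.75) (adjusted p = 0.00134, but adjusted p = 0.127 with an estimated correlation). Proximal tubule genes moved up in 6 of 20, with Aqp1 (2.32) (adjusted p = 0.00412, but adjusted p = 0.236 with an estimated correlation). Podocyte genes moved up in 4 of 14 with 1 lower (adjusted p = 0.00713, but adjusted p = 0.337 with an estimated correlation). Intercalated cell genes moved up in 5 of 11 (adjusted p = 0.00401, but adjusted p = 0.236 with an estimated correlation). Principal cell genes moved down in 4 of 12, led by Aqp4 (−4.22), and up in 1, Aqp2 (adjusted p = 0.00158, but adjusted p = 0.112 with an estimated correlation). Early nephron had 3 of 10 up and 1 down (adjusted p = 0.0192, but adjusted p = 0.321 with an estimated correlation), and distal tubule 3 of 10 up (adjusted p = 0.0219, but adjusted p = 0.127 with an estimated correlation). Ureteric tip had 2 of 8 up (adjusted p = 0.0494, but adjusted p = 0.302 with an estimated correlation) and embryonic stroma 4 of 10 up (adjusted p = 0.00599, but adjusted p = 0.112 with an estimated correlation). Cell cycle had 0 of 12 up (adjusted p = 0.014, but adjusted p = 0.302 with an estimated correlation) and hypoxia 2 of 11 up (adjusted p = 0.00576, but adjusted p = 0.236 with an estimated correlation). Sterol synthesis had 1 of 12 up (adjusted p = 9.55e-06, but adjusted p = 0.163 with an estimated correlation) and fatty acid oxidation 1 of 12 down (adjusted p = 0.0322, but adjusted p = 0.24 with an estimated correlation). In total 1831 genes differed, 1055 up and 776 down.

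**Figure D3:**
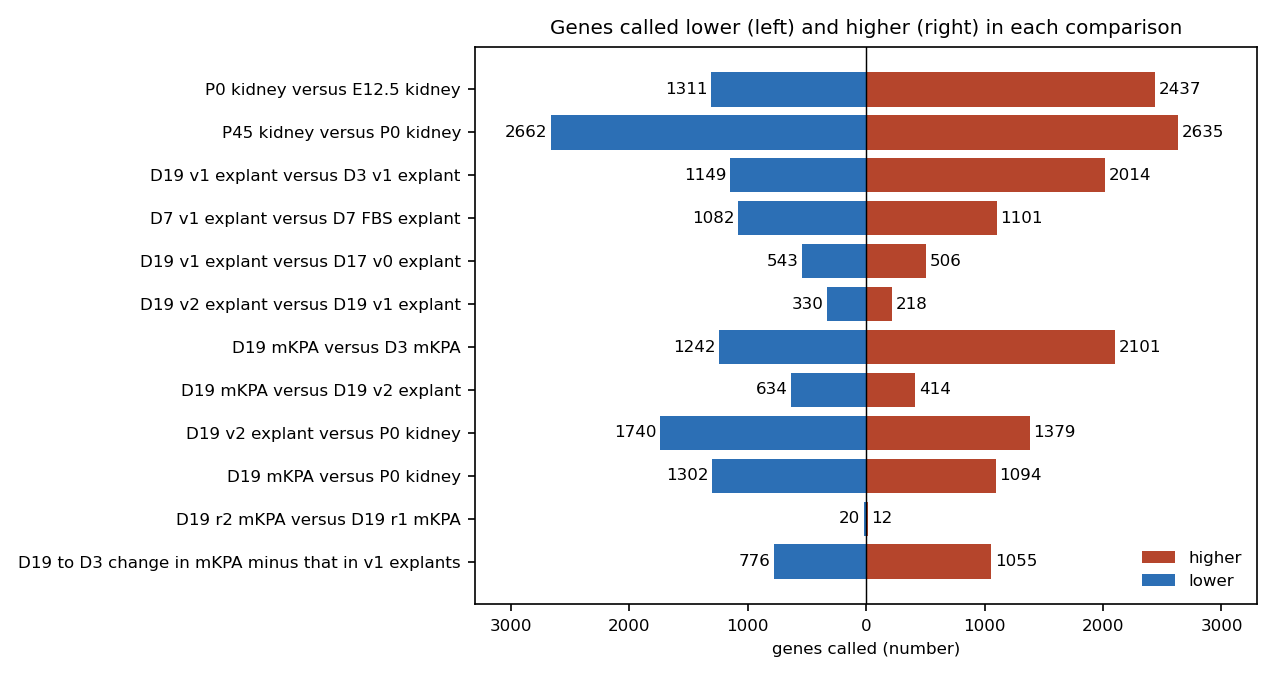
Number of genes past both thresholds in each of the 12 comparisons, with bars to the right for higher and to the left for lower in the first-named group. The counts run from 32 for r2 against r1 to 5297 for P45 against P0.

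Each cultured group was correlated with each kidney stage across 19264 genes, which are not independent replicates, and no test was made. By Pearson correlation of log2 values 9 of the 12 cultured groups were closest to E15.5 and 3 to P0. Those closest to P0 were D19 v1 explants (0.937 ± 0.000597), D19 r1 assembloids (0.938 ± 0.0014) and D19 r2 assembloids (0.943 ± 3.47e-05, SD over n = 2 libraries). Their values for E15.5 were 0.933, 0.932 and 0.937, so the margins were small. D19 v2 explants stood at 0.9238 for E15.5 and 0.9236 for P0. Margins were small towards E12.5 too, with D3 v1 explants at 0.9655 for E15.5 and 0.9638 for E12.5. D3 assembloids stood at 0.9474 and 0.9448 for these stages. With Spearman correlation, or with the 7082 genes that differed between kidney stages, 8 groups were closest to E15.5 and 4 to P0.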

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

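The test of whether the D3 to D19 change differed between assembloids and v1 explants was planned. No test in this part was chosen after its result was seen, and the genes and lists follow from the naming rule and from both list tests. The 2 cultures differ in origin and in medium, and Y-linked transcripts were present in D3 and at the lowest step in D19 assembloids, so the source of the cells may differ with the day. Of the genes tested, 1831 differed. The log2 difference of the changes, assembloids minus explants, was 6.54 for Ren1 and 4.60 for Penk. Ren1 stood at 0.287 ± 0.0520 in D3 (SD, n = 2) and 127 ± 118 in D19 assembloids (SD, n = 4), and at 0.914 ± 0.446 and 0.661 ± 0.496 in D3 and D19 v1 explants (SD, n = 2 each). In D19 explants in v2, the medium of the assembloids, it stood at 333 and 210, so high Ren1 at D19 was not confined to assembloids.

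The endothelial genes had differences of 5.39 for Pecam1, 5.06 for Sox7, 4.94 for Cdh5 and 4.76 for Cldn5, and the endothelial list had a median of 2.97. Pecam1 was low in assembloids on both days, 0.187 ± 0.193 (SD, n = 2) and 0.445 ± 0.254 (SD, n = 4), and fell in explants from 77.3 ± 11 to 1.33 ± 0.393 (SD, n = 2 each). The matrix list had a median difference of 1.90. The immune list had −1.72, with C1qa at the lowest step in assembloids on both days, so that its fitted values are no bounds.

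Differences in the other direction were −11.15 for Gsdmc3, −10.86 for Gsdmc2, −7.51 for Sprr1a, −7.31 for Ctse, −6.20 for Sprr2f and −5.81 for Sprr2a3. Gsdmc3, Gsdmc2, Ctse and Sprr2a3 fell in assembloids and rose in explants. Sprr1a fell in assembloids, with a log2 change of 0.31 in explants, and Sprr2f rose in explants, with −0.28 in assembloids. The Gsdmc and Sprr genes have near-identical relatives, and their separate values are uncertain.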

How the results depend on the processing

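The settings that left out ribosomal protein genes, pseudogenes, Y-linked genes and Xist, and camera without its variance trend, were chosen after seeing the data; the others were planned. The counts of calls that moved by more than 1.5 times follow. With 4 times the pseudocount, which shrinks changes of low genes, the counts were 2461 for P0 against E12.5, 2067 for D19 against D3 v1 explants, 1249 for v1 against serum, 516 for v1 against v0, 259 for v2 against v1, 440 for assembloids against v2 explants, 1912 and 1440 for v2 explants and assembloids against P0, 15 for r2 against r1 and 1032 for the difference of changes. With the pseudocount divided by 4 they were 1630 for assembloids against v2 explants and 9 for r2 against r1. A filter on the mean, which left 13172 genes, gave 1434 for v1 against serum, 686 for v1 against v0 (401 higher and 285 lower), 362 for v2 against v1, 552 for assembloids against v2 explants and 11 for r2 against r1. With only its groups in the fit, limma gave 0 for r2 against r1, with 1873 at an unadjusted p under 0.05; the cause was not tested. Leaving out single libraries gave 6 to 37 genes for r2 against r1.

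With an estimated correlation camera called 5, 7, 6, 1, 0, 2, 1, 3, 10, 8, 0 and 3 lists, in the order in which the comparisons were described, against 17, 13, 16, 6, 7, 11, 15, 9, 16, 17, 10 and 19 with the preset. Where it called 0 lists, 5 (v1 against v0) and 7 (r2 against r1) had an unadjusted p under 0.05. Without the variance trend camera called 18 lists for the difference of changes and the same number as the main setting elsewhere. Of 624 list medians under quantile normalization or equal totals, 19 changed sign, 0 of them in lists past the preset test.

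Same-numbered replicates deviated together with correlations of −0.205 to 0.205, so the numbers were not taken as pairs. With the replicate number as a block the counts were 3748, 5296, 3165, 2186, 1047, 548, 3344, 1049, 3120, 2397, 31 and 1842, and the counts of lists changed to 18 for assembloids against P0 and 20 for the difference of changes. Since the fold threshold sets most counts, these and the counts without trend say little about stability. For named genes, 4427 of 4452 values under other settings kept their direction and side of the threshold, 25 lost the call, 0 gained it and 0 reversed. The naming rule favours the largest changes of the main fit, so these figures say little about other called genes. Genes near 1 step are limited by depth, most so in the library of 7772154 steps.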

Other observations

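The tests of the shallow library, of scaling, of Y-linked genes, of near-identical copies and of strain were chosen after the results were seen. The cAMP, retinoid and glucocorticoid lists were added after the patterns they bear on had been seen. Their predictions, and that for the depth of the lower library, were written before these tests were run. The p-values of the added lists are not adjusted. The D7 and D13 assembloids, the D13 v1 explants and the E15.5 and P9 kidneys entered the correlations with kidney stages but none of the 12 comparisons. The genes below were chosen after their values were seen, with no test between days. In assembloids Six2 stood at 161 ± 48.6 at D3, 163 ± 4.19 at D7 and 159.5 ± 2.36 at D13 (SD, n = 2 each), and at 59.4 ± 14.8 at D19 (SD, n = 4). Ret, the receptor of the ureteric tip, stood at 178 ± 8.67 at D13 (SD, n = 2) and 25.0 ± 3.87 at D19 (SD, n = 4). The salt cotransporter Slc12a1 stood at 1.06 ± 0.749 and 83.3 ± 27.3 on these days, and Ren1 at 0.522 ± 0.320 and 127 ± 118. The proximal tubule carrier Slc34a1 stood at 2.63 ± 0.594, 8.03 ± 2.18 and 40.8 ± 3.23 at D7, D13 and D19. Y-linked Ddx3y stood at 4.94 to 10.2 in the D3 to D13 assembloids and at 1 step in those of D19. Day and cell source may therefore differ together between D13 and D19.

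In kidneys Slc34a1 stood at 142 ± 5.32 at E15.5 and 1176 ± 2.02 at P9, uromodulin (Umod) at 4.92 ± 1.04 and 1438 ± 77.4, and Six2 at 115 ± 10.3 and 0.467 ± 0.205 (SD, n = 2 each). Ren1 was at 69.5 ± 1.73 at E15.5. Tubb3, a tubulin of neurons, stood at 31.5 ± 20.7 in D13 v1 explants and 0.217 ± 0.223 in D13 assembloids (SD, n = 2 each).

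Ren1, Akr1b7, Aqp2 and Fosb, picked after their values were seen, were higher in D19 v2 than in D19 v1 explants. Their median log2 change was 3.01 without the shallow v2 replicate 2, which argues against depth of that library as the whole cause. It was at least 2.98 under equal totals or quantile normalization. These moved the median of all genes only from −0.065 to −0.0414 and −5e-04, too little to bear on changes of this size. A cAMP-responsive program may be part of the pattern. The 10 genes of a separate list had a median log2 change of 0.46 (camera with an estimated correlation, p = 0.0026). That change is small beside the pattern, only Pde4d (1.30) passed both thresholds, and the difference between the media is not given in the sources used here. Fos (2.03), an immediate early gene like Fosb, was higher in this comparison too. The list test does not separate a cAMP response from a general immediate early response. The medium itself remains an open explanation.

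The Y-linked gene Ddx3y stood at 4.94 to 10.2 in the 6 assembloid libraries of D3 to D13 and at 1 step in all 4 of D19, while Xist was at least 1435 in all 10. At the mean of the earlier level, a D19 library would hold at least 113 steps of Ddx3y, which argues against depth. The lowest ratio of Ddx3y to its X-linked relative Ddx3x in the earlier libraries was 81.0 times the highest at D19, which argues against misplaced X-linked reads. All 4 of the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty showed the split, so that male cells among the D3 to D13 assembloids alone are a candidate source. No sex is given for the assembloids in the sources used here, and no biological explanation other than the source of the cells was tested.

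Among 11885 genes with a value of at least 20, 72 differed at least 8-fold between the replicates of a group, 41 of them ribosomal protein genes or pseudogenes, against 501 of all those eligible (odds ratio 32.6, 95% interval 19.7 to 54.3, p = 5.55e-38, Fisher's exact test). Without the D19 v2 explants, 10 of 34 such genes were of these kinds (odds ratio 10.45, interval 4.43 to 22.8, p = 4.22e-07, Fisher's exact test). Of 102 low values 33.3% lay in the shallower library of the pair. This share cannot decide on depth. The largest step was 0.11881, so a value of at least 20 spans many steps in every library. The D19 v2 explants, with the shallowest library, also gave 45 of the 102 and weigh heavily on the share. Reads placed on one or another near-identical copy may account for many of these genes. Among the widest differences were those of Xist and the same 4 Y-linked genes. In D3, D13 and D19 v1 explants Xist was at least 1237 in replicate 1, with the Y-linked genes at 1 step, and at most 0.319 in replicate 2, with Ddx3y at least 76.3. In D19 v2 explants Xist was 0.164 in replicate 1 and 854 in replicate 2, with Ddx3y at 113 and 2.495. Replicates of opposite sex show such values. In kidneys Xist was 0.0429 and 340.3 in the P0 replicates and 186.5 and 0.216 in those of E15.5, with Ddx3y at least 36.95 in each, as where only 1 replicate of a pair holds female cells. No sex is given for explants or kidneys in the sources used here. For ribosomal protein genes and pseudogenes a strain variant cannot be told apart from reads placed on copies, since Rpl29 was under 5 in 11 libraries and between 5 and 50 in 0, and strain is not given per sample.

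Cyp26b1 (7.30), Cyp26a1 (3.37) and Lrat (4.70) were higher in D7 v1 than in serum explants, the second chosen after its value was seen. A retinoid-responsive program may be higher in v1, as a hypothesis. In a separate list of such genes the median log2 change was 1.41 (camera with an estimated correlation, p = 0.000538). Of 7 tested members 4 were higher, among them Stra6 (2.38), Dhrs3 (2.16) and Rarb (1.77), while Rdh10 was −0.80.

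Zbtb16 (5.00) and Fkbp5 (2.32), the latter chosen after its value was seen, were higher in D19 v1 than in D17 v0 explants. A glucocorticoid-responsive program may be higher in v1, as a hypothesis. In a separate list of 9 such genes, 1 of which the cAMP list also holds, the median log2 change was 0.97 (camera with an estimated correlation, p = 0.00471). Of these 4 were higher, Ddit4 (1.43), Per1 (1.38), Sgk1 (1.37) and Cebpd (1.01). Day and medium differ together here, and the composition of both media is not given in the sources used here.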
